A study of Escherichia coli str. K-12 substr. MG1655 with 10 samples.

How the data were processed

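Gene expression was measured by RNA sequencing in 10 cultures of Escherichia coli that carried a plasmid with the insert ORF1, a plasmid with a recoded Svi3-3 insert, or pCA24N without an insert. Groups were taken from the sample labels. They were the empty plasmid with IPTG, ORF1 without and with IPTG, and Svi3-3 without and with IPTG, with 2 cultures each. Per the labels, overnight cultures were diluted into M9 medium with 0.2% glucose and 5 µg/mL chloramphenicol, 20 mL per culture, and induced cultures received 50 µM IPTG. Cells were taken at an optical density of 0.15 to 0.2, RNA was stabilized and purified with column kits, and libraries were made with a TruSeq kit and sequenced as total RNA at a sequencing company, per the labels. The labels' titles name the strain MG1655 and their growth protocol names DA4201. Proteomics of the same cultures was not used here.

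The deposited table holds, for each library and gene, a count of mapped reads, a coverage value and an RPKM value (reads per kilobase of gene length per 1000000 mapped reads), per the file headers. The aligner, the counting program, its use of strand and the genome build are not given in the sources used here. The counts deposited by the authors were whole numbers, and their sums equalled the totals in the file headers in all 10 libraries. In the deposited count columns 228 values were printed as a dash. The smallest printed count was 1, and a dash was read as 0. The deposited RPKM values equalled the count divided by gene length and by the header total to within a relative deviation of 5.1e-15, so they carry no scaling beyond library total and length. The coverage percent deposited by the authors reached 104.92 and was used only to describe single genes. Of the listed gene lengths 99.48% were multiples of 3, as in coding lengths, and the shortest was 102 bases. Of 4205 genes listed, 4200 matched a locus tag of the RefSeq gene table of assembly ASM584v2, which was used for names, gene types and neighbours only. Among them 4077 were protein-coding and 123 pseudogenes, and 221 symbols differed from the table, in which case the symbol of the deposited table was kept. No ribosomal or transfer RNA genes were listed. Transcripts of the plasmid inserts were not analysed here.

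Total counts ranged from 7.07 to 8.34 per library, in units of 1000000 reads. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and the groups as design, which left 4085 genes. Library sizes were scaled by the trimmed mean of M values (TMM), with factors of 0.839 to 1.115. A quasi-likelihood model with 1 mean per group was fitted to all 10 libraries, so that the spread was shared over 5 residual degrees of freedom. The common dispersion was 0.0506 and the prior degrees of freedom were 3.83. Each standard error is the absolute log2 fold change divided by the square root of the F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as counts per 1000000 reads (CPM) after TMM scaling, as the mean and SD of 2 libraries. Genes with near-identical copies, such as argF and argI, are uncertain, as are overlapping genes and antisense pairs, since the treatment of shared reads and strand is not given.

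The comparisons were induced ORF1 and induced Svi3-3 against the empty plasmid, induced against uninduced cultures within each insert, uninduced cultures against the empty plasmid, induced ORF1 against induced Svi3-3, and the interaction of insert and inducer. Gene lists, 33 in number and fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Of 601 members written in the lists, 599 were in the table. ahcY and tisB were not matched. For the overlap of responses that share the empty plasmid libraries, 20 simulations of unchanged groups were run.

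Named genes followed a rule fixed in advance. It took metA, metB, metC, metE, metF, metI, metJ, metK, metL, metN, metQ, metR, ilvA and lacZ in every comparison. Per comparison it added the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among called genes whose libraries did not overlap between the groups and whose mean count was at least 50, and up to 4 called members per list. For the interaction the condition on overlap did not apply.

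Alternatives were other scalings (DESeq2 size factors, total count), DESeq2 1.42.0, limma with trend on log2(RPKM + 1) and log2(RPKM + 0.1), no filter and a stricter filter at a mean count of 50, a fit of the compared libraries only, replicate blocks, an adjusted p under 0.01, a test against a fold change of 1.5, and leaving out each library in turn. After the data had been seen, a fit without the uninduced ORF1 replicate 2 and uninduced Svi3-3 replicate 1 libraries (called the chosen libraries) was added from the principal components. Other libraries also lay apart, with replicate 1 of induced Svi3-3 lowest on component 2 (-25, replicate 2 -4.9) and replicate 1 of induced ORF1 highest on component 1 (27.1, replicate 2 21.4). These were left out singly only. A crossed pairing of the ORF1 cultures was also added, as were, for the overlaps, fits without either empty plasmid library and with 1 of these libraries for each insert, and, for named genes, a block for each culture.

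Scripts were tested on 5 simulations of 4045 genes on average, 200 of them changed. For induced ORF1 against the empty plasmid, edgeR recovered 34%, 91.6% and 97.9% of genes changed 2, 4 and 8-fold, with 4.7% false calls. Shares were 31%, 89.9% and 97.3% for induced against uninduced ORF1 (6% false) and 10%, 71.6% and 93% for the interaction (5.7% false). DESeq2 gave 7% to 9.7% false calls in 1 simulation. In 5 of 5 simulations camera at either correlation and fry called a 14-gene list changed 4-fold in induced Svi3-3 against the empty plasmid. Whether these hold with unequal spread or correlated genes was not tested.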

Results

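Transcript levels were measured in 10 cultures of Escherichia coli K-12 MG1655 that carried either the empty expression vector pCA24N or a plasmid with an insert whose expression is switched on by IPTG. The inserts were ORF1 and a recoded Svi3-3. Both plasmids came from a selection for constructs that restore growth of cells without ilvA, the gene for threonine deaminase in isoleucine synthesis. Cultures with the empty plasmid received 50 µM IPTG. Cultures with either insert were grown with IPTG (called induced here) and without it (uninduced), which gave 5 groups of 2 cultures in minimal medium with 0.2% glucose. The empty plasmid without IPTG was not analysed here, so a comparison of an uninduced insert with the empty plasmid differs in the inducer too. Total counts were lowest in replicate 2 of induced ORF1 and highest in replicate 2 of induced Svi3-3, and 4085 genes were tested. Cultures of a group were separate, and p-values use a spread pooled over all 5 groups.

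The single gene metE, for the cobalamin-independent methionine synthase, took 7.11% and 9.14% of all counts in the libraries of induced ORF1 and 7.06% and 9.59% in those of induced Svi3-3. It was also the most abundant gene in replicate 2 of uninduced ORF1, with 2.44% of counts. Replicates of the empty plasmid were closer (SD of their log2 difference across genes 0.297) than those of insert groups (0.47 to 0.611). Comparisons among insert groups share the pooled spread, so their p-values may be too small. Chi-square per gene between replicates was 7.4 to 145.3, and no group was treated as 1 library deposited again. Scaling by total count instead of TMM moved the median log2 fold change of all genes by -0.21 for induced ORF1 and by -0.24 for induced Svi3-3 against the empty plasmid. The shift was -0.26 for induced against uninduced Svi3-3, -0.14 for uninduced ORF1 against the empty plasmid, 0.19 for the interaction and -0.07 to 0.04 otherwise. Changes below are relative to TMM scaling.

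The comparison of induced ORF1 with the empty plasmid at the same IPTG concentration asked which host genes differ when this insert is expressed. Genes for methionine synthesis rose most. metE (b3829) went from 488 ± 48.8 CPM (SD, n = 2) with the empty plasmid to 86810 ± 17400 CPM (SD, n = 2), a 178-fold difference (log2 fold change 7.48 ± 0.57 SE, edgeR adjusted p = 0.00021). metF (b3941), for methylenetetrahydrofolate reductase, rose 98.4-fold from 53.5 ± 17 to 5268 ± 79.7 CPM (SD, n = 2; edgeR adjusted p = 9.4e-05). metA (b4013), for homoserine O-succinyltransferase, rose 79.4-fold from 45.4 ± 5.33 to 3606 ± 693 CPM (SD, n = 2; edgeR adjusted p = 0.00014). All 14 members of the list of genes repressed by MetJ, the repressor that binds S-adenosylmethionine, were higher, also when adjusted over the list alone (median log2 fold change 4.29, camera adjusted p = 6e-94, and adjusted p = 0.012 with an estimated correlation). They included metJ itself (b3938; 6.75-fold, edgeR adjusted p = 0.00031), metK (b2942) for S-adenosylmethionine synthetase (8.04-fold, edgeR adjusted p = 0.0033), mmuP (b0260) for a putative S-methylmethionine transporter (43.4-fold) and the methionine uptake genes metN (b0199), metI (b0198) and metQ (b0197), at 13, 9.13 and 9.11-fold. metB, metC, metL and metR rose 39.6, 13.4, 22 and 22.7-fold. Outside the list, ybdL (b0600), for a methionine aminotransferase, rose 43.6-fold (log2 fold change 5.45 ± 0.52 SE, edgeR adjusted p = 0.00062).

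Genes for sulfur uptake were also higher with induced ORF1. Of 9 genes for taurine and sulfonate use, 6 rose and 3 did not pass, with 8 higher when adjusted over the list alone (median log2 fold change 2.93, camera adjusted p = 3e-24, adjusted p = 0.076 with an estimated correlation). tauA (b0365), for a taurine transporter subunit, went from 1.95 ± 0.556 to 82.7 ± 44.4 CPM (SD, n = 2; log2 fold change 5.40 ± 0.47 SE, edgeR adjusted p = 0.00037), and tauB, tauC and ssuA rose 41.6, 20.9 and 7.83-fold. Of 18 genes for sulfate assimilation and cysteine, 3 rose and 15 did not pass, with 15 higher when adjusted over the list alone (median 1.58, camera adjusted p = 7.8e-14, adjusted p = 0.23 with an estimated correlation). These were sbp (b3917), for a periplasmic sulfate-binding protein, from 41.5 ± 7.92 to 1228 ± 437 CPM (SD, n = 2; 29.6-fold, edgeR adjusted p = 0.0016), cbl (b1987), for an activator of the taurine and sulfonate operons (11-fold), and cysN (b2751), for a sulfate adenylyltransferase subunit (4.67-fold, edgeR adjusted p = 0.034). The sulfate count was 1 without either empty plasmid library, 7 without either uninduced ORF1 library, 6 without either uninduced Svi3-3 library, 12 without both chosen libraries, 14 with DESeq2 and 15 in a fit of the compared libraries only. The call of cysN ended with total-count scaling, with limma on RPKM and without any library of either group. cbl, ssuA and metQ lost their calls without either empty plasmid library, metK without replicate 2 of it, and ssuA also without replicate 2 of induced ORF1 and without both chosen libraries.

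Genes of the SOS response to DNA damage, which LexA represses, rose in 11 of 19 members, and 8 did not pass. Adjusted over the list alone 17 were higher (median 1.79, camera adjusted p = 9e-46, adjusted p = 0.012 with an estimated correlation). recN (b2616), for a DNA repair protein, went from 79.5 ± 6.37 to 1005 ± 99.1 CPM (SD, n = 2; log2 fold change 3.66 ± 0.23 SE, edgeR adjusted p = 0.00014). sulA (b0958), for the inhibitor of cell division, umuD (b1183), for a subunit of DNA polymerase V, and dinD (b3645) rose 7.65, 7.5 and 6.67-fold. The SOS count was 17 in a fit of the compared libraries only. Of 18 genes for colanic acid, an envelope polysaccharide, and its Rcs regulation, 3 rose and 15 did not pass, with 6 higher when adjusted over the list alone (median 0.78, camera adjusted p = 1.1e-06, adjusted p = 0.028 with an estimated correlation). They were wcaD (b2056; 4.23-fold), rcsA (b1951; 2.43-fold) and gmd (b2053; 2.23-fold). Of 17 envelope stress genes, pspG (b4050; 4.89-fold) and cpxP (b4484; 2.35-fold) rose and 15 did not pass, with 5 higher when adjusted over the list alone (median 0.48, camera adjusted p = 1.4e-05, adjusted p = 0.053 with an estimated correlation). Of 10 genes for serine, glycine and one-carbon units, 4 rose and 6 did not pass, and the count adjusted over the list alone was also 4 (median 0.55, camera adjusted p = 7.2e-06, adjusted p = 0.27 with an estimated correlation). These were gcvP (b2903), gcvH (b2904) and gcvT (b2905) of the glycine cleavage system, at 11, 10.4 and 9.98-fold, and glyA (b2551), for serine hydroxymethyltransferase, at 2.41-fold (edgeR adjusted p = 0.037). In the list for use and recycling of S-adenosylmethionine, metH (b4019), for the cobalamin-dependent methionine synthase, rose 3.22-fold (edgeR adjusted p = 0.0035) and 10 of 11 members did not pass, with 5 higher when adjusted over the list alone (median 0.28, camera adjusted p = 0.0012, adjusted p = 0.2 with an estimated correlation). Without either empty plasmid library, 0 of the named genes of the colanic acid, envelope stress, one-carbon and S-adenosylmethionine lists passed. wcaD, rcsA, gmd, cpxP and glyA did not pass without either library of induced ORF1, and pspG did not without replicate 1 of it. rcsA, gmd and cpxP did not with total-count scaling or limma on RPKM, the last of which also ended the call of wcaD.

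Phosphate uptake genes fell with induced ORF1. Of 17 genes of the phosphate starvation list, 6 were lower and 11 did not pass, with 8 lower when adjusted over the list alone (median -0.71, camera adjusted p = 1.4e-14, adjusted p = 0.11 with an estimated correlation). pstA (b3726), for a subunit of the high-affinity phosphate transporter, went from 349 ± 36.5 to 50.1 ± 6.75 CPM (SD, n = 2; log2 fold change -2.80 ± 0.33 SE, edgeR adjusted p = 0.002). phoU (b3724), for the negative regulator of the PhoR and PhoB system, fell 7.43-fold from 571 ± 40.4 to 76.8 ± 5.2 CPM (SD, n = 2; edgeR adjusted p = 0.0045). pstC (b3727), pstS (b3728), pstB (b3725) and phoR (b0400), for the sensor kinase, fell 6.35, 6.12, 5.86 and 2.47-fold. Other genes that fell were gltP (b4077), for a glutamate and aspartate transporter (3.19-fold), dtpA (b1634), for a peptide permease (2.54-fold), ydgI (b1605; 2.45-fold) and oppA (b1243), for the oligopeptide-binding protein (2.36-fold, edgeR adjusted p = 0.04). oppA was the 1 called member of 17 in the list for uptake of branched-chain amino acids and peptides, of which 2 were lower when adjusted over the list alone (median -0.36, camera adjusted p = 0.032, adjusted p = 0.61 with an estimated correlation). The camera call of that list ended without replicate 1 of the empty plasmid or of uninduced ORF1 or replicate 2 of induced ORF1 (adjusted p = 0.05 to 0.28). The number of phosphate genes called was 3 without replicate 1 of the empty plasmid, 2 and 3 without replicates 1 and 2 of induced ORF1, and 12 in a fit of the compared libraries only. pstS, gltP, dtpA, phoR, ydgI and oppA each did not pass without any one of the 4 compared libraries, pstC did not without replicate 1 of the empty plasmid or either library of induced ORF1, and phoU did not without replicate 1 of induced ORF1. phoR also did not with limma on RPKM, nor oppA without both chosen libraries.

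**Figure D1:**
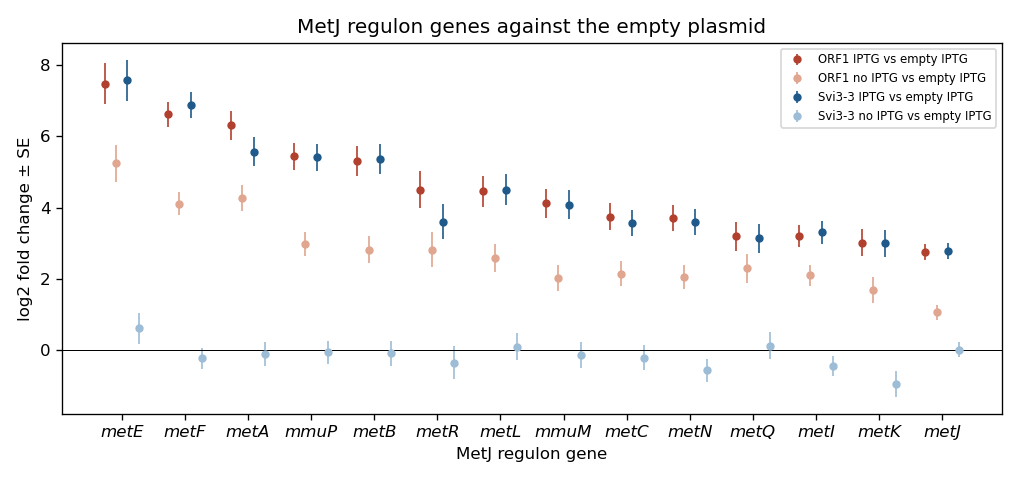
Log2 fold change against the empty plasmid (vertical axis) of the 14 genes in the MetJ list (horizontal axis), with bars of 1 SE from the edgeR fit and a colour for each of the 4 insert groups. With either induced insert all 14 genes lay above 0, with metE at 7.48 for ORF1 and 7.57 for Svi3-3; uninduced ORF1 lay between (metE 5.25) and uninduced Svi3-3 lay near 0 (metE 0.61, not called).

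Over all genes, 79 were higher and 15 lower with induced ORF1 than with the empty plasmid. The split was 63 higher and 31 lower with total-count scaling and 60 and 31 with limma on RPKM, so that the share of higher calls was 84% with TMM and 67% with total count. ilvA (b3772) was at 188 ± 4.16 CPM with the empty plasmid and 121 ± 15.4 CPM (SD, n = 2) with induced ORF1 and did not pass (log2 fold change -0.63 ± 0.18 SE, edgeR adjusted p = 0.12). lacZ (b0344), for beta-galactosidase, did not pass either (1.26 ± 0.32 SE, edgeR adjusted p = 0.091). The 94 calls became 49 at an adjusted p under 0.01, 55 in the test against a 1.5-fold change, 266 with DESeq2, 615 in a fit of the 4 compared libraries only and 168 without both chosen libraries. They numbered 34 and 36 without replicate 1 and replicate 2 of the empty plasmid and 50 without replicate 1 of induced ORF1.

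In 8 further lists the list test passed without a called member. Across their 195 genes edgeR called 0, against 66 at an unadjusted p under 0.05, 48 with DESeq2 and 1 with limma on RPKM. Medians were higher for iron uptake under Fur (1.97, camera adjusted p = 7.6e-16), histidine biosynthesis (1.59, camera adjusted p = 1.1e-06), iron-sulfur cluster assembly (0.83, camera adjusted p = 1.2e-07) and sugar uptake (0.32, camera adjusted p = 0.0042). They were lower for arginine biosynthesis (-1.82, camera adjusted p = 1.4e-06), curli and type 1 fimbriae (-0.44, camera adjusted p = 0.024), anaerobic respiration and fermentation (-0.25, camera adjusted p = 0.0066) and ribosomal proteins (-0.22, camera adjusted p = 0.0052). None of these 8 held with an estimated correlation (adjusted p = 0.27 to 0.73), and the camera call of the fimbriae ended without replicate 1 of induced ORF1 (adjusted p = 0.32). Adjusted over the list alone, all 8 histidine genes, 27 of 34 iron uptake genes, 10 of 14 iron-sulfur genes and 4 of 32 sugar uptake genes were higher. The level of the iron uptake and arginine lists varied between replicates, with median log2 CPM of 6.72 and 5.94 for iron uptake and 7.19 and 10.46 for arginine biosynthesis in the induced ORF1 libraries. Another 15 lists did not pass (camera adjusted p = 0.067 to 0.97, medians -0.12 to 0.6). They were isoleucine, valine and leucine, threonine and lysine, threonine and serine breakdown, lac, tryptophan and aromatic biosynthesis, glutamate and nitrogen, purines, pyrimidines, flagella, heat shock, the RpoS general stress response, acid resistance, oxidative stress, the TCA cycle and cryptic prophages. Among their 245 genes edgeR called 1, which was lysC (b4024), for the lysine-sensitive aspartokinase (6.13-fold higher, edgeR adjusted p = 0.018), with 34 at an unadjusted p under 0.05, 13 with DESeq2 and 1 with limma on RPKM. The call of lysC ended without either empty plasmid library and without replicate 1 of induced ORF1.

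Induced Svi3-3 against the empty plasmid asked the same question of the other insert. The methionine genes again rose most. metE went to 92810 ± 30500 CPM (SD, n = 2), 190-fold above the empty plasmid (log2 fold change 7.57 ± 0.58 SE, edgeR adjusted p = 0.00033), metF to 6351 ± 1120 CPM (SD, n = 2; 119-fold, edgeR adjusted p = 7.4e-05) and metA to 2162 ± 524 CPM (SD, n = 2; 47.6-fold, edgeR adjusted p = 0.00032). All 14 members of the MetJ list were higher, also when adjusted over the list alone (median 3.84, camera adjusted p = 8.3e-143, adjusted p = 0.0058 with an estimated correlation). mmuP, metB, metL, metR, metN and metC rose 42.8, 41.2, 22.7, 12.2, 12.1 and 11.9-fold, and metI, metQ, metK and metJ rose 9.85, 8.8, 7.97 and 6.85-fold. Outside the list, ybdL and ybdH (b0599), for a putative oxidoreductase, rose 40.1 and 20.7-fold. Of 18 sulfate and cysteine genes 12 rose and 6 did not pass, with 16 higher when adjusted over the list alone (median 2.24, camera adjusted p = 3.5e-35, adjusted p = 0.1 with an estimated correlation). sbp reached 2065 ± 865 CPM (SD, n = 2; 49.8-fold), and cbl, cysN and cysD (b2752) rose 14.1, 7.87 and 7.38-fold. Of 9 taurine and sulfonate genes 4 rose and 5 did not pass, with 7 higher when adjusted over the list alone (median 2.23, camera adjusted p = 2.5e-22, adjusted p = 0.11 with an estimated correlation). These were tauA, tauB, tauC and tauD (b0368), for taurine dioxygenase, at 22.7, 16.8, 11.3 and 5.16-fold.

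The SOS list rose with induced Svi3-3 too, with 12 of 19 members higher and 7 not passing, and 15 higher when adjusted over the list alone (median 1.46, camera adjusted p = 1.3e-48, adjusted p = 0.01 with an estimated correlation). recN reached 635 ± 0.125 CPM (SD, n = 2; log2 fold change 3.00 ± 0.23 SE, edgeR adjusted p = 0.00033), and sulA, umuD and dinD rose 5.59, 5.18 and 4.81-fold. gcvT rose 4.68-fold (edgeR adjusted p = 0.037) as the 1 called gene of 10 in the one-carbon list, of which 4 were higher when adjusted over the list alone (median 0.3, camera adjusted p = 0.0029, adjusted p = 0.69 with an estimated correlation). metH rose 2.37-fold as the 1 called gene of its list, which did not pass (camera adjusted p = 0.53). The largest fall was that of flu (b2000), for the autotransporter antigen 43, from 972 ± 103 to 38.5 ± 0.676 CPM (SD, n = 2; log2 fold change -4.66 ± 0.38 SE, edgeR adjusted p = 0.00036). Its neighbour yeeR (b2001) fell 3.16-fold, zraP (b4002), for a zinc-dependent periplasmic chaperone, 2.86-fold, and pstA 3.1-fold to 112 ± 52.5 CPM (SD, n = 2; edgeR adjusted p = 0.037). pstA was the 1 called member of the 17 phosphate genes, of which 7 were lower when adjusted over the list alone (median -0.43, camera adjusted p = 1.3e-07, adjusted p = 0.4 with an estimated correlation). pstA kept its call without replicate 1 of induced Svi3-3 and lost it without any other single library, with total-count scaling, without both chosen libraries, in the test against a 1.5-fold change and in a fit of the compared libraries only. The phosphate count was 6 with DESeq2 and 5 without replicate 1 of induced Svi3-3. zraP lost its call without replicate 1 of the empty plasmid, any ORF1 library, either library of induced Svi3-3 or both chosen libraries.

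Over all genes 69 were higher and 4 lower with induced Svi3-3, and these 4 were flu, yeeR, zraP and pstA. ilvA was at 194 ± 25.8 CPM (SD, n = 2; log2 fold change 0.04 ± 0.18 SE, edgeR adjusted p = 1) and lacZ at 169 ± 19.1 CPM (SD, n = 2; 0.10 ± 0.32 SE, edgeR adjusted p = 1). Purine biosynthesis (median -0.36, camera adjusted p = 0.027) and heat shock (median -0.47, camera adjusted p = 0.0013) passed the list test as lower, with adjusted p = 0.97 with an estimated correlation for both. The purine median was 7.89 and 9.22 log2 CPM in replicates 1 and 2 of induced Svi3-3 against 8.82 and 8.68 with the empty plasmid, and without replicate 1 the list test pointed higher (camera adjusted p = 0.76). Its call also ended without replicate 1 of the empty plasmid or of uninduced ORF1 (adjusted p = 0.078 and 0.054), and those of heat shock and one-carbon units ended without replicate 2 of induced Svi3-3 (camera adjusted p = 0.27 and 0.14). edgeR called 0 of their 32 genes, with 1 at an unadjusted p under 0.05 and 0 with DESeq2 and with limma on RPKM. The other 25 lists did not pass (camera adjusted p = 0.052 to 0.95). Without either empty plasmid library the named methionine genes metQ and metR, and metH, cbl, cysN, cysD, tauC, tauD, gcvT and pstA lost their calls, as did metK without replicate 2 of it. All calls numbered 31 and 33 in those fits and 46 without replicate 2 of induced Svi3-3, where metH, cysD and gcvT were lost, and 44 at an adjusted p under 0.01. gcvT also lost its call with total-count scaling, with limma on RPKM, without both chosen libraries, and without either library of induced ORF1 or of uninduced Svi3-3. The sulfate count was 1 without either empty plasmid library, 7 and 4 without replicates 1 and 2 of induced Svi3-3, 6 in the test against a 1.5-fold change, and 7 with total-count scaling and with limma on RPKM. The taurine count was 2 without either empty plasmid library, and the SOS count was 7 without replicate 1 of it.

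**Figure D2:**
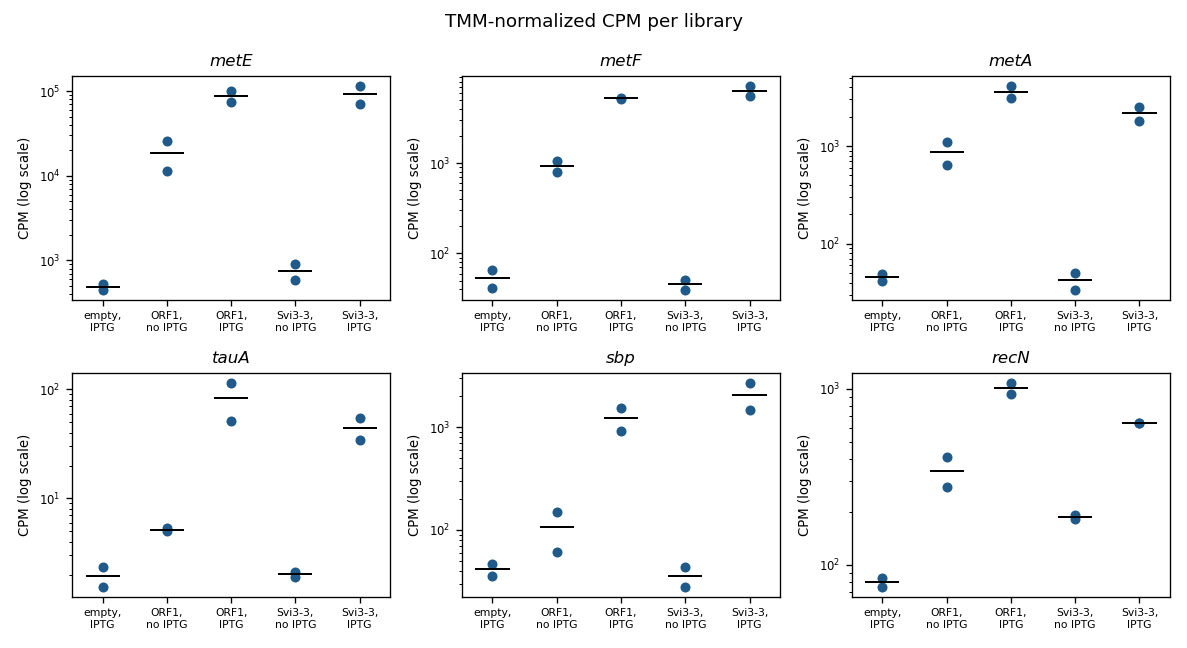
Level of metE, metF, metA, tauA, sbp and recN in each of the 10 libraries, in TMM-normalized CPM on a log axis, by group, with a bar at the mean of the 2 libraries. In both induced insert groups each of the 6 genes lay above the empty plasmid, with mean metE of 86810 CPM for ORF1 and 92810 CPM for Svi3-3 against 488 CPM.

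Induced against uninduced ORF1 asked what IPTG changed in cells with this plasmid. Taurine genes rose most. tauC (b0367) rose 19-fold, tauB (b0366) 16.2-fold, and tauA 16-fold, from 5.15 ± 0.237 to 82.7 ± 44.4 CPM (SD, n = 2; log2 fold change 4.00 ± 0.43 SE, edgeR adjusted p = 0.01). With tauD (7.39-fold) they were the 4 called of 9 taurine and sulfonate genes, and 8 were higher when adjusted over the list alone (median 2.22, camera adjusted p = 1.9e-35, adjusted p = 0.04 with an estimated correlation). sbp rose 11.6-fold from 106 ± 63.5 CPM (SD, n = 2; edgeR adjusted p = 0.026) as the 1 called of 18 sulfate and cysteine genes, with 15 higher when adjusted over the list alone (median 1.38, camera adjusted p = 1.1e-21, adjusted p = 0.13 with an estimated correlation). Of the 14 MetJ genes 6 rose and 8 did not pass, and all 14 were higher when adjusted over the list alone (median 1.79, camera adjusted p = 4.1e-43, adjusted p = 0.04 with an estimated correlation). The 6 were metF (5.69-fold, edgeR adjusted p = 0.013), metB (5.61-fold), mmuP (5.51-fold), mmuM (4.25-fold), metA (4.13-fold) and metJ (3.25-fold). metE was at 18550 ± 10000 CPM (SD, n = 2) without IPTG and did not pass (log2 fold change 2.23 ± 0.45 SE, edgeR adjusted p = 0.088), nor did metC, metI, metK, metL, metN, metQ and metR (log2 fold changes 0.90 to 1.88, edgeR adjusted p = 0.088 to 0.63). ybdH rose 4.52-fold.

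lacZ, which IPTG induces (plasmid reads not excluded), rose 4.49-fold in ORF1 cultures from 83.6 ± 36.8 to 376 ± 133 CPM (SD, n = 2; log2 fold change 2.17 ± 0.33 SE, edgeR adjusted p = 0.029). It was the 1 called of 3 lac operon genes, and all 3 were higher when adjusted over the list alone (median 1.33, camera adjusted p = 3.3e-08, adjusted p = 0.04 with an estimated correlation). Of 19 SOS genes 5 rose and 14 did not pass, with 14 higher when adjusted over the list alone (median 0.88, camera adjusted p = 2e-23, adjusted p = 0.04 with an estimated correlation). They included recN (2.94-fold from 342 ± 93 CPM; SD, n = 2), umuD (2.45-fold), umuC (b1184; 2.14-fold) and yebG (b1848; 2.1-fold). dtpA (2.89-fold), oppA (2.71-fold, from 7064 ± 119 to 2607 ± 384 CPM; SD, n = 2) and yeeR (2.23-fold) fell. oppA was the 1 called of 17 genes for uptake of branched-chain amino acids and peptides, with 3 lower when adjusted over the list alone (median -0.87, camera adjusted p = 6.5e-07, adjusted p = 0.4 with an estimated correlation). In total 23 genes were higher and 3 lower. ilvA did not pass (log2 fold change -0.21 ± 0.18 SE, edgeR adjusted p = 0.85).

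Another 11 lists passed the list test for this comparison with 0 of their 236 genes called by edgeR, 35 at an unadjusted p under 0.05, 4 with DESeq2 and 0 with limma on RPKM. Colanic acid was higher (median 0.57, camera adjusted p = 1.5e-05, adjusted p = 0.04 with an estimated correlation), with 3 of 18 members higher when adjusted over the list alone. Histidine biosynthesis (0.66), iron uptake (0.43), iron-sulfur assembly (0.42), one-carbon units (0.37), heat shock (0.31) and envelope stress (0.28) had higher medians, and arginine biosynthesis (-0.9), glutamate and nitrogen (-0.53), sugar uptake (-0.34) and ribosomal proteins (-0.32) lower ones. For these 10 the adjusted p was 0.14 to 0.67 with an estimated correlation. Camera calls of arginine, iron uptake, iron-sulfur assembly, heat shock and envelope stress ended without replicate 1 of induced ORF1 (adjusted p = 0.096 to 0.88), and those of glutamate and nitrogen, histidine, heat shock and envelope stress without replicate 2 of uninduced ORF1 (adjusted p = 0.067 to 0.37). With replicate 1 of it left out, one-carbon units did not pass and iron uptake pointed lower (adjusted p = 0.066 and 0.07). The remaining 16 lists, phosphate starvation among them, did not pass (camera adjusted p = 0.11 to 0.82). The 26 calls became 10 with total-count scaling or limma on RPKM, 79 with DESeq2, 5 in the test against a 1.5-fold change, 1 at an adjusted p under 0.01, 10 without both chosen libraries and 0 in a fit of the 4 compared libraries only. With a block for each culture 10 genes were called and 9 of the 20 named calls were kept, while those of metA, metB, mmuP, mmuM, sbp, ybdH, umuD, umuC, yebG, oppA and yeeR ended. Total-count scaling and limma on RPKM each ended the calls of metA, metJ, mmuM, lacZ, recN, umuD, umuC, yebG, oppA and yeeR, and without both chosen libraries those of metB, mmuP, mmuM, ybdH and tauB were kept. In the fit of all libraries 315 genes were at an unadjusted p under 0.05. Of the 20 named genes called, tauB kept its call without any single library. All calls numbered 5 without either empty plasmid library, 14 and 6 without replicates 1 and 2 of uninduced ORF1, and 4 and 5 without replicates 1 and 2 of induced ORF1. The MetJ count was 1 without either empty plasmid library, 2 without replicate 1 of uninduced ORF1 and 0 without either library of induced ORF1. It was 13 with DESeq2, 3 with total-count scaling or limma on RPKM, 1 in the test against a 1.5-fold change and 0 in the fit of the compared libraries. The taurine count was 2 and 1 without replicates 1 and 2 of uninduced ORF1, 1 without both chosen libraries, 8 with DESeq2 and 0 in the fit of the compared libraries. The SOS count was 9 with DESeq2. It was 0 with total-count scaling, with limma on RPKM, in the test against a 1.5-fold change, in the fit of the compared libraries and without both chosen libraries. It was also 0 without either empty plasmid library, replicate 2 of uninduced ORF1 or either library of induced ORF1, 1 without replicate 1 of uninduced ORF1, and 3 without either library of induced Svi3-3. The calls of sbp and lacZ ended without either empty plasmid library, replicate 2 of uninduced ORF1 or either library of induced ORF1. The sulfate count was 10 with DESeq2, 2 without either library of uninduced Svi3-3, and 0 without both chosen libraries, in the test against a 1.5-fold change and in the fit of the compared libraries.

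Induced against uninduced Svi3-3 asked what IPTG changed in cells with that plasmid. metF rose 140-fold from 45.4 ± 7.87 CPM (SD, n = 2; log2 fold change 7.13 ± 0.37 SE, edgeR adjusted p = 6e-05), metE 125-fold from 744 ± 218 CPM (SD, n = 2; edgeR adjusted p = 0.00041), ybdL 63.1-fold and metA 51.3-fold. All 14 MetJ genes rose, also when adjusted over the list alone (median 4.2, camera adjusted p = 1.2e-148, adjusted p = 0.0068 with an estimated correlation), with mmuP and metB at 44.6 and 44.1-fold, metL, metN, metR, metK, metC and metI at 21.3, 18, 15.6, 15.5, 13.8 and 13.5-fold, and metQ and metJ at 8.12 and 6.79-fold. ybdH rose 20.1-fold. Of 18 sulfate and cysteine genes 14 rose and 4 did not pass, with 16 higher when adjusted over the list alone (median 2.56, camera adjusted p = 7.8e-43, adjusted p = 0.1 with an estimated correlation). They included sbp (58.1-fold), cbl (19-fold), cysH (b2762; 9.59-fold) and cysC (b2750; 9.11-fold). Of 9 taurine and sulfonate genes 4 rose and 5 did not pass, with 6 higher when adjusted over the list alone (median 2.72, camera adjusted p = 4.1e-23, adjusted p = 0.12 with an estimated correlation). These were tauA, tauC, tauB and tauD, at 21.8, 13, 12.7 and 7.26-fold. Of 19 SOS genes 4 rose and 15 did not pass, with 12 higher when adjusted over the list alone (median 0.69, camera adjusted p = 2.6e-12, adjusted p = 0.12 with an estimated correlation). They were recN (3.4-fold from 187 ± 6.64 CPM; SD, n = 2), yebG (2.18-fold), umuC (1.95-fold) and dinB (b0231; 1.82-fold). gcvT rose 5.14-fold as the 1 called of 10 one-carbon genes, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0049, adjusted p = 0.67 with an estimated correlation). The median of that list was 0.16 with TMM and -0.11 with total-count scaling.

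In all, 61 genes were higher and 0 lower with edgeR, with 191 higher and 90 lower at an unadjusted p under 0.05, 88 higher and 11 lower with DESeq2, and 44 higher and 1 lower with limma on RPKM. lacZ went from 57.4 ± 2.31 to 169 ± 19.1 CPM (SD, n = 2) and did not pass (log2 fold change 1.55 ± 0.33 SE, edgeR adjusted p = 0.068), nor did ilvA (-0.25 ± 0.18 SE, edgeR adjusted p = 0.85). Lists that passed with no called member were histidine biosynthesis (median 1.03, camera adjusted p = 8.2e-05), the lac operon (0.57, camera adjusted p = 0.014), tryptophan and aromatic biosynthesis (0.34, camera adjusted p = 0.037), flagella and chemotaxis (-0.24, camera adjusted p = 0.012) and phosphate starvation (-0.75, camera adjusted p = 1.1e-08, 7 of 17 lower when adjusted over the list alone). The camera call of histidine ended without replicate 1 of uninduced Svi3-3, that of flagella without replicate 2 of induced Svi3-3, and that of lac without replicate 1 of induced or 2 of uninduced Svi3-3 (adjusted p = 0.071 to 0.12). The aromatic call ended without replicate 2 of induced or 1 of uninduced Svi3-3 or either of uninduced ORF1 (adjusted p = 0.082 to 0.62), and the one-carbon call without replicate 2 of either Svi3-3 group (adjusted p = 0.053 and 0.068). For the 5 lists the adjusted p was 0.31 to 0.98 with an estimated correlation, and of their 93 genes edgeR called 0, with 17 at an unadjusted p under 0.05, 7 with DESeq2 and 0 with limma on RPKM. The other 23 lists did not pass (camera adjusted p = 0.066 to 0.93). The 61 calls became 33 at an adjusted p under 0.01, 99 with DESeq2, 31 in a fit of the compared libraries only and 36 without both chosen libraries, and they numbered 25 without replicate 1 of uninduced and 36 without replicate 2 of induced Svi3-3. The sulfate count was 8 with total-count scaling and in the test against a 1.5-fold change, 5 in the fit of the compared libraries, and 9 without both chosen libraries. It was 7 and 8 without replicates 1 and 2 of the empty plasmid, 2 without replicate 1 of uninduced and 8 and 4 without replicates 1 and 2 of induced Svi3-3. metQ lost its call without either library of uninduced Svi3-3 and metR without replicate 1 of it, and gcvT without either library of the empty plasmid or of uninduced Svi3-3 and without replicate 2 of induced Svi3-3, without both chosen libraries and with limma on RPKM. The taurine count was 2 without both chosen libraries, where tauA, tauC and cysH lost their calls. The SOS count was 7 with DESeq2 and 0 in the fit of the compared libraries. It was 1 with total-count scaling, with limma on RPKM, in the test against a 1.5-fold change, without both chosen libraries and without replicate 1 of uninduced or replicate 2 of induced Svi3-3, and 2 without any other single library.

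Uninduced ORF1 was set against the empty plasmid to find what differed without IPTG, with the reservation that the empty plasmid cultures held IPTG. Methionine genes were higher here too. metE was 38-fold above the empty plasmid (log2 fold change 5.25 ± 0.52 SE, edgeR adjusted p = 0.0051), metA 19.2-fold at 873 ± 332 CPM (SD, n = 2; edgeR adjusted p = 0.0028) and metF 17.3-fold at 926 ± 186 CPM (SD, n = 2; edgeR adjusted p = 0.002). Of the 14 MetJ genes 11 were higher and 3 did not pass, with all 14 higher when adjusted over the list alone (median 2.43, camera adjusted p = 1.7e-73, adjusted p = 0.041 with an estimated correlation). mmuP, metR, metB, metL, metQ, metC, metI and metN were 7.87, 7.07, 7.06, 5.98, 4.89, 4.4, 4.27 and 4.13-fold higher, while metK (log2 fold change 1.68 ± 0.36 SE, edgeR adjusted p = 0.14) and metJ (1.06 ± 0.22 SE, edgeR adjusted p = 0.12) did not pass. ybdL and ybdH were 8.13 and 5.02-fold higher. Of 19 SOS genes 8 rose and 11 did not pass, with 11 higher when adjusted over the list alone (median 0.77, camera adjusted p = 1.8e-23, adjusted p = 0.061 with an estimated correlation). They included recN (4.3-fold), dinI (b1061; 3.62-fold), sulA (3.23-fold) and umuD (3.07-fold). Of 17 phosphate genes 4 fell and 13 did not pass, with 8 lower when adjusted over the list alone (median -0.64, camera adjusted p = 2e-20, adjusted p = 0.099 with an estimated correlation). These were pstC (6.02-fold), pstA (5.8-fold, to 60.1 ± 11.3 CPM; SD, n = 2), phoU (5.4-fold, to 106 ± 41.3 CPM; SD, n = 2) and pstB (5.39-fold). metH was 2.7-fold higher as the 1 called member of its list of 11, with 1 also when adjusted over the list alone (median 0.23, camera adjusted p = 0.0033, adjusted p = 0.22 with an estimated correlation).

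The sulfate and cysteine list did not pass in uninduced ORF1 (median 0.18, camera adjusted p = 0.3). Among the 17 lists that passed with no called member were taurine and sulfonate use (median 0.33, camera adjusted p = 0.03), sugar uptake (0.77, camera adjusted p = 2.4e-16, 12 of 32 higher when adjusted over the list alone), iron uptake (1.66, camera adjusted p = 2.4e-12), pyrimidines (0.82, camera adjusted p = 3.5e-05), histidine (0.94, camera adjusted p = 0.00019), glutamate and nitrogen (0.49, camera adjusted p = 0.015), the lac operon (-0.81, camera adjusted p = 0.0021) and arginine (-0.99, camera adjusted p = 0.014). The others were one-carbon units, purines, iron-sulfur assembly, colanic acid, envelope stress and the TCA cycle, which were higher, and acid resistance, anaerobic respiration and fimbriae, which were lower (camera adjusted p = 0.0021 to 0.03). The iron uptake median was 4.23 and 6.73 log2 CPM in replicates 1 and 2 of uninduced ORF1 against 4.07 and 4.12 with the empty plasmid, and that of glutamate and nitrogen was 5.05 and 6.91 against 5.5 and 5.44. Without replicate 2 the camera calls of iron uptake, arginine, purines, iron-sulfur assembly, the TCA cycle, anaerobic respiration, colanic acid and taurine ended (adjusted p = 0.14 to 0.73), and glutamate and nitrogen pointed lower (adjusted p = 0.95). Those of taurine, colanic acid, acid resistance, fimbriae and envelope stress ended without replicate 1 (adjusted p = 0.088 to 0.2), and those of anaerobic respiration, acid resistance and purines without 1 of the empty plasmid libraries (adjusted p = 0.061 to 0.093). For all 17 the adjusted p was 0.19 to 0.67 with an estimated correlation, and of their 269 genes edgeR called 0, with 77 at an unadjusted p under 0.05, 14 with DESeq2 and 0 with limma on RPKM. The other 12 lists did not pass (camera adjusted p = 0.067 to 0.77). Over all genes 23 were higher and 4 lower. The split was 17 and 5 with total-count scaling and 16 and 6 with limma on RPKM. ilvA (log2 fold change -0.43 ± 0.18 SE, edgeR adjusted p = 0.6) and lacZ (-0.91 ± 0.32 SE, edgeR adjusted p = 0.48) did not pass. The 27 calls became 64 with DESeq2, 11 in the test against a 1.5-fold change, 7 at an adjusted p under 0.01, and 13 without both chosen libraries. They numbered 1 and 0 without replicates 1 and 2 of the empty plasmid, 49 and 11 without replicates 1 and 2 of uninduced ORF1, and 13 without either library of induced ORF1. In those fits the MetJ count was 1 and 0 without the empty plasmid libraries, 6 without replicate 2 of uninduced ORF1, 5 without either library of induced ORF1, 7 without either library of uninduced Svi3-3, 5 in the test against a 1.5-fold change, 7 without both chosen libraries and 4 in a fit of the compared libraries only. The SOS count was 0 without either empty plasmid library, 4 without either library of uninduced ORF1, 5 without either library of induced ORF1, without both chosen libraries and in a fit of the compared libraries only, 3 in the test against a 1.5-fold change and 4 with total-count scaling or limma on RPKM. The phosphate count was 0 without either empty plasmid library or replicate 2 of uninduced ORF1, 2 without either library of induced ORF1 and in the test against a 1.5-fold change, 0 without both chosen libraries, 7 in a fit of the compared libraries only and 8 with DESeq2. Calls of metQ, metR and sulA ended with total-count scaling and limma on RPKM, that of metC with limma, and those of metC, metL, metQ, metR, metH, ybdL and the 4 phosphate genes without both chosen libraries. metF was the 1 named gene that kept its call without replicate 1 of the empty plasmid, and 0 of the 22 named genes called did without replicate 2 of it.

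Uninduced Svi3-3 differed from the empty plasmid in 2 called genes, both lower. flu was at 40.03 ± 0.0342 CPM (SD, n = 2; log2 fold change -4.60 ± 0.37 SE, edgeR adjusted p = 0.0031) and yeeR at 8.47 ± 1.16 CPM (SD, n = 2; -2.10 ± 0.21 SE, edgeR adjusted p = 0.0074). edgeR called 0 genes higher, with 67 at an unadjusted p under 0.05, 8 with DESeq2 and 0 with limma on RPKM. The MetJ list did not pass (median -0.13, camera adjusted p = 0.22), with metE at 0.61 ± 0.43 SE and metK at -0.96 ± 0.36 SE (edgeR adjusted p = 0.93 for both). The other MetJ genes named in every comparison lay between -0.58 and 0.12. ilvA (0.29 ± 0.18 SE, edgeR adjusted p = 0.93) and lacZ (-1.45 ± 0.33 SE, edgeR adjusted p = 0.49) did not pass. The SOS list was higher (median 0.66, camera adjusted p = 2.6e-25, adjusted p = 0.1 with an estimated correlation), with 12 of 19 members higher when adjusted over the list alone. recN was at 187 ± 6.64 CPM (SD, n = 2) against 79.5 ± 6.37 CPM (SD, n = 2) with the empty plasmid. Lower medians were found for histidine (-0.69, camera adjusted p = 3.6e-05), the lac operon (-0.54, camera adjusted p = 0.0025), purines (-0.35, camera adjusted p = 0.0035), tryptophan and aromatic biosynthesis (-0.34, camera adjusted p = 0.0022) and sulfate and cysteine (-0.26, camera adjusted p = 0.037), each with an adjusted p of 0.62 to 0.9 with an estimated correlation. All 5 of these calls ended without 1 library of uninduced Svi3-3, which was replicate 2 for lac (camera adjusted p = 0.22) and replicate 1 for the others (camera adjusted p = 0.48 to 0.77, with purines and sulfate pointing higher). The histidine median was 6.58 and 8.27 log2 CPM in replicates 1 and 2 against 8.45 and 8.3 with the empty plasmid, and the purine median 7.94 and 9.03 against 8.82 and 8.68. The sulfate call also ended without replicate 1 of the empty plasmid or of induced Svi3-3 (camera adjusted p = 0.33 and 0.059). Of the 80 genes of these 6 lists edgeR called 0, with 14 at an unadjusted p under 0.05, 8 with DESeq2 and 0 with limma on RPKM. The other 27 lists did not pass (camera adjusted p = 0.12 to 0.95). The call of yeeR ended without either empty plasmid library, leaving 1 call, both calls ended without replicate 1 of uninduced Svi3-3, and 7 genes were called without replicate 2 of it. DESeq2 called 13 genes, and 1 was called in a fit of the compared libraries only and without both chosen libraries.

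**Figure D3:**
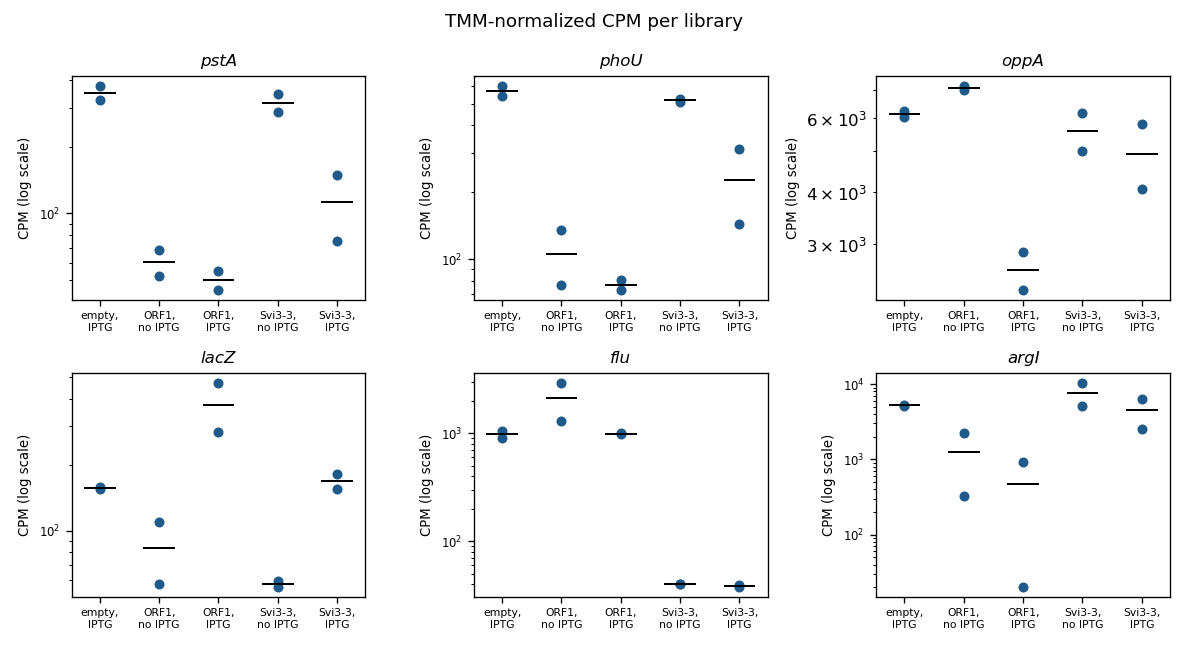
Level of pstA, phoU, oppA, lacZ, flu and argI in each of the 10 libraries, in TMM-normalized CPM on a log axis, by group, with a bar at the mean of the 2 libraries. flu lay between 38.1 and 40.1 CPM in the 4 Svi3-3 libraries and between 899.9 and 2896 CPM in the other 6. argI, a gene similar to argF and chosen after its values were seen, spread from 20.4 to 919 CPM within induced ORF1.

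The direct comparison of the induced inserts asked whether they differ at the same IPTG concentration. flu was 25.6-fold higher with ORF1 (log2 fold change 4.68 ± 0.38 SE, edgeR adjusted p = 0.0028) and was the 1 gene called. edgeR called 0 genes lower, with 159 at an unadjusted p under 0.05, 18 with DESeq2 and 0 with limma on RPKM. The 14 MetJ genes did not pass as a list (median 0.02, camera adjusted p = 0.63). metA (0.74 ± 0.33 SE), metR (0.90 ± 0.45 SE), metE (-0.10 ± 0.43 SE) and metF (-0.27 ± 0.28 SE) did not pass (edgeR adjusted p = 0.49 to 0.95), and the other MetJ genes named in every comparison lay between -0.11 and 0.18. ilvA (-0.67 ± 0.18 SE, edgeR adjusted p = 0.28) and lacZ (1.16 ± 0.32 SE, edgeR adjusted p = 0.29) did not pass. Lists that were higher with ORF1 included colanic acid (median 0.73, camera adjusted p = 3.4e-08, 4 of 18 higher when adjusted over the list alone) and envelope stress (0.45, camera adjusted p = 9e-09, 7 of 17), both with adjusted p = 0.029 with an estimated correlation. Further lists were iron uptake (2, camera adjusted p = 1.4e-33, 31 of 34), histidine (1.25, camera adjusted p = 2.4e-08, 8 of 8), iron-sulfur assembly (0.67, camera adjusted p = 1.4e-13, 11 of 14), heat shock (0.64, camera adjusted p = 6.5e-08, 9 of 17), pyrimidines (0.91, camera adjusted p = 0.00016), taurine (0.88, camera adjusted p = 8.8e-05), purines (0.57, camera adjusted p = 0.00013) and SOS (0.23, camera adjusted p = 0.00052, 3 of 19), with counts adjusted over the list alone. Lower lists were arginine (-1.84, camera adjusted p = 2.3e-08), sulfate and cysteine (-0.65, camera adjusted p = 0.00016), phosphate starvation (-0.6, camera adjusted p = 3.9e-06) and ribosomal proteins (-0.3, camera adjusted p = 1.4e-05). The S-adenosylmethionine, one-carbon, lac and prophage lists also passed as higher (camera adjusted p = 0.00073 to 0.047). For these 16 lists the adjusted p was 0.26 to 0.65 with an estimated correlation. Camera calls of purines, pyrimidines, taurine and one-carbon units ended without replicate 1 of induced Svi3-3 (adjusted p = 0.055 to 0.5), and the last 3 also without replicate 2 of induced ORF1 (adjusted p = 0.082 to 0.29). With replicate 2 of induced Svi3-3 left out, SOS did not pass and ribosomal proteins pointed higher (adjusted p = 0.056 and 0.49). The lac call ended without replicate 1 of induced ORF1 or any Svi3-3 library (adjusted p = 0.055 to 0.31), and the prophage call without replicate 2 of either induced group or either library of uninduced ORF1 (adjusted p = 0.059 to 0.22). Across the 300 genes of all 18 lists edgeR called 0, with 109 at an unadjusted p under 0.05, 42 with DESeq2 and 0 with limma on RPKM. The other 15 lists did not pass (camera adjusted p = 0.11 to 0.85). The call of flu ended without replicate 2 of induced Svi3-3, 2 genes were called without replicate 1 of it, and DESeq2 called 71 genes higher and 18 lower.

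The interaction asked whether the response to IPTG differed between the inserts. metF was the 1 gene called, with a response 4.62 ± 0.42 SE log2 units smaller for ORF1 than for Svi3-3 (value -4.62, edgeR adjusted p = 0.0071). Values for metE (-4.74 ± 0.64 SE, edgeR adjusted p = 0.064), metA (-3.63 ± 0.47 SE, edgeR adjusted p = 0.064), metI (-2.66 ± 0.41 SE, edgeR adjusted p = 0.086) and metB (-2.97 ± 0.51 SE, edgeR adjusted p = 0.16) did not pass. The MetJ list was lower (median -2.58, camera adjusted p = 7.4e-67, adjusted p = 0.051 with an estimated correlation), with 1 of 14 called and all 14 lower when adjusted over the list alone. ilvA (0.05 ± 0.26 SE, edgeR adjusted p = 0.97) and lacZ (0.62 ± 0.45 SE, edgeR adjusted p = 0.91) did not pass. edgeR called 0 genes higher, with 73 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma on RPKM. Another 14 lists passed with 0 of 285 genes called by edgeR, 21 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with limma on RPKM. Lower lists were peptide uptake (-1.25, camera adjusted p = 9.4e-05), sulfate and cysteine (-1.22, camera adjusted p = 1.5e-08), glutamate and nitrogen (-0.88), arginine (-0.65), sugar uptake (-0.63, camera adjusted p = 2.1e-05) and ribosomal proteins (-0.33). Higher lists were heat shock (0.66, camera adjusted p = 3.2e-05), the lac operon (0.62), phosphate starvation (0.61, camera adjusted p = 3.2e-05), iron uptake (0.38), colanic acid (0.37), oxidative stress (0.36), iron-sulfur assembly (0.28) and envelope stress (0.17). For these 14 the adjusted p was 0.22 to 0.84 with an estimated correlation. The camera calls of peptide uptake, sulfate, heat shock and phosphate held without any single library. Those of the other 10 each ended without at least 1 library (adjusted p = 0.051 to 0.9), and each of the 8 libraries with an insert ended at least 1 of them. Arginine pointed higher without replicate 1 of induced ORF1, iron uptake lower without replicate 1 of uninduced ORF1, and ribosomal proteins higher without replicate 2 of induced Svi3-3. The other 18 lists, SOS (camera adjusted p = 0.2) and taurine (camera adjusted p = 0.54) among them, did not pass. The call of metF ended without either library of induced ORF1, without replicate 1 of uninduced Svi3-3, without both chosen libraries and with a block for each culture. Calls numbered 13 without replicate 1 of uninduced ORF1, of which 10 were MetJ genes, 6 without replicate 2 of uninduced Svi3-3, 2 with total-count scaling or limma on RPKM and 22 with DESeq2, 13 of them MetJ genes.

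The responses to IPTG of the ORF1 and Svi3-3 cultures compare separate libraries, with a spread estimated over all 10. Across the 4085 genes, which are not independent replicates, their log2 fold changes had a Pearson correlation of 0.435 and a Spearman correlation of 0.124, and 51.8% of genes had the same sign. Of the 23 genes higher in ORF1 and the 61 higher in Svi3-3, 17 were shared, where independent lists of these sizes would share 0.34. Among them were the 6 called MetJ genes, tauA, tauB, tauC, tauD, sbp, ybdH, recN, umuC, dinB and yebG. edgeR called 0 genes lower in Svi3-3, against 90 at an unadjusted p under 0.05, 11 with DESeq2 and 1 with limma on RPKM. The shared number was 9 and 6 without replicates 1 and 2 of uninduced ORF1, 4 without either library of induced ORF1 and 5 without either empty plasmid library. Against the empty plasmid, 49 genes were higher with both induced inserts, where independent lists would share 1.3. Simulated groups held no changed gene, so 0 shared there decides nothing. The 1 gene lower in both, pstA, compares with 0.015 for independent lists, and its call with Svi3-3 ended with total-count scaling. The correlation of log2 fold changes was 0.671 against 0.486 in the simulations, and their covariance was 0.254 against 0.0655, a difference of 0.188. Signs agreed for 65.5% of genes against 66.4% in the simulations. With 1 of the 2 empty plasmid libraries for each insert, a fit chosen after the data were seen, 26 and 27 genes were higher with both inserts in the 2 assignments, where independent lists would share 0.22 and 0.23. Covariance was then 0.235 and 0.227, correlation 0.574 and 0.544, signs agreed for 61.7% and 58.8%, and pstA was not called with both.

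The list calls that held with an estimated correlation depended on single libraries. For induced ORF1 the MetJ p was 0.051 and 0.064 without replicates 1 and 2 of induced Svi3-3, the SOS p was 0.051, 0.051 and 0.065 without replicate 2 of uninduced ORF1 and replicates 1 and 2 of induced Svi3-3, and the colanic acid p was 0.046 to 0.083 and passed only without replicate 2 of the empty plasmid. For induced Svi3-3 the MetJ call held without any single library (adjusted p = 0.0009 to 0.046), and the SOS p was 0.091 and 0.085 without replicates 1 and 2 of induced Svi3-3. For induced against uninduced Svi3-3 the MetJ p was 0.14 without replicate 2 of uninduced and 0.081 without replicate 1 of induced Svi3-3. For uninduced ORF1 the MetJ p was 0.0073 and 0.0085 without replicates 1 and 2 of uninduced ORF1 and 0.075 to 0.12 without any other library. In induced against uninduced ORF1 the calls of MetJ, taurine, SOS, lac and colanic acid ended without any single library, with a p of 0.058 to 0.13, except that of MetJ without replicate 2 of uninduced ORF1 (adjusted p = 0.019). Those of colanic acid and envelope stress between the induced inserts also ended without any single library, with a p of 0.052 to 0.24. In every list that passed camera at the preset correlation, the median and the mean had the sign of the test.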

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

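The tests of this part, of mixing and of swapped labels, were chosen only after the result was seen. The response of metF to IPTG differed between the inserts, with a value of -4.62 on the log2 scale for ORF1 minus Svi3-3 (SE 0.42, edgeR adjusted p = 0.0071), and the call ended with a block for each culture. The part of this difference that lies in the uninduced ORF1 cultures was weighed, where the MetJ genes stood between the empty plasmid and the induced cultures. Mixing of induced cells or reads into the uninduced ORF1 libraries would raise all induced genes by 1 share of their induced level. Across the 4 pairs of uninduced and induced library the median share was 14.51% to 33.69% for the MetJ genes, with lower quartiles of 10.9% to 25.66%, and 29.13% to 38.39% for the SOS genes, but at most 5.89% for the 6 called taurine and sulfonate genes. The highest single taurine gene reached 6.07% to 26.1%, inside the MetJ quartiles in 2 of the 4 pairs, so the medians argue against mixing as the whole cause and leave a small mixed share open. A swap of induced and uninduced labels among the ORF1 libraries is argued against by a gap of 1.6 log2 CPM between the lowest induced and the highest uninduced MetJ median, where replicates differed by at most 0.84. Some expression of the ORF1 insert without IPTG stays open and was not tested, since the insert's reads were not analysed here.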

How the results depend on the processing

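Most alternatives below were chosen before the data were examined. Fits without both chosen libraries, with crossed pairing or with a block for each culture came after. So did the overlaps without an empty plasmid library or with these split. None of the 153 calls of named genes reversed, but some list tests did. Of those calls, 153 kept direction and side of the threshold with DESeq2, 131 with total-count scaling, 128 with limma on log2(RPKM + 1) and 114 without both chosen libraries. They numbered 79 to 145 when a single library was left out, with the lowest number without either empty plasmid library. Comparisons are given in the order induced ORF1 and induced Svi3-3 against the empty plasmid, induced against uninduced ORF1 and Svi3-3, uninduced ORF1 and Svi3-3 against the empty plasmid, induced ORF1 against induced Svi3-3, and the interaction. Calls numbered 94, 73, 26, 61, 27, 2, 1 and 1.

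Only counts that moved over 1.5 times follow, with their order kept. DESeq2 called 266, 79, 99, 64, 13, 89 and 22 genes, with no such move for induced Svi3-3 against the empty plasmid. An adjusted p under 0.01 left 49, 44, 1, 33 and 7 in the first 5 comparisons, which follows from the threshold. Fits of the compared libraries only called 615 for induced ORF1 against the empty plasmid, 0 and 31 within ORF1 and Svi3-3, and 1 for uninduced Svi3-3. The test against a 1.5-fold change left 55, 5 and 11 for induced ORF1 against the empty plasmid, induced against uninduced ORF1 and uninduced ORF1. Total-count scaling and both limma fits each gave 10 within ORF1 and 2 for the interaction. Without both chosen libraries the calls were 168 for induced ORF1 against the empty plasmid, 10 and 36 within ORF1 and Svi3-3, 13 and 1 for uninduced ORF1 and Svi3-3, and 0 for the interaction. Fewer libraries went with rises too (615 and 168), and no cause beyond the threshold was tested.

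Leaving out each library in turn gave 34 to 138, 31 to 74, 4 to 32, 25 to 77, 0 to 49, 0 to 7, 0 to 2 and 0 to 13 calls. A group with 1 library left was assumed to vary like the other groups. The list test with camera passed for 18, 8, 17, 10, 21, 6, 18 and 15 lists, and for 18 to 21, 7 to 13, 13 to 23, 9 to 14, 13 to 22, 5 to 8, 16 to 20 and 11 to 17 when a library was left out. With an estimated correlation it passed for 3, 2, 5, 1, 1, 0, 2 and 0 lists, and with fry, which tests whether a list moves 1 way without reference to other genes, for 10, 2, 5, 4, 4, 1, 2 and 0. The 17 genes higher in both responses to IPTG were 16 with DESeq2 size factors, 17 without a filter and 4 to 17 when a library was left out.

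Labels give the same replicate numbers to all groups. They describe duplicate overnight cultures diluted into the cultures of each insert, without saying that a number marks a shared overnight culture or day. Deviations of same-numbered libraries correlated at -0.18 between the ORF1 groups and 0.54 between the Svi3-3 groups, so the numbers were not taken to pair the libraries. With the replicate block, calls numbered 96, 73, 19, 65, 25, 2, 1 and 1, lists 19, 9, 17, 11, 21, 5, 16 and 15, shared genes 14, and 141 of 153 named calls were kept. The block changed no count of calls over 1.5 times. It ended the 12 other named calls and, with an estimated correlation, the list calls within ORF1, in uninduced ORF1 and between the induced inserts, added envelope stress for induced ORF1, and changed no other of these calls. With a block for each culture the counts were 10 and 51 within ORF1 and Svi3-3 and 0 for the interaction, and 34 of 49 named calls there were kept. Crossed numbers of the ORF1 cultures gave 76 calls against 10 as numbered.

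Counts of calls stayed within 1.5 times with DESeq2 size factors, without a filter and with the stricter filter in all 8 comparisons. No ribosomal or transfer RNA genes could be left out, as none is listed. At this depth and with 2 libraries per group, 2-fold changes can be missed, as 34% were recovered in simulations for induced ORF1 against the empty plasmid and 10% for the interaction.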

Other observations

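All tests of this part were chosen after the results were seen, as were fepA, entC, fhuF, argI, glnK and plaP, outside the naming rule. fepA, for the outer membrane receptor of ferric enterobactin, was at 19 to 25.4 CPM in 7 libraries, at 264 CPM in replicate 2 of uninduced ORF1 and at 720.5 and 93.6 CPM in replicates 1 and 2 of induced ORF1. entC and fhuF, also iron uptake genes, were highest in the same 3 libraries, with entC at 282, 401 and 122 CPM there and 9.4 to 22.6 CPM elsewhere. argI, for ornithine carbamoyltransferase, went the other way, at 324.5 CPM in replicate 2 of uninduced ORF1, 20.4 and 919 CPM in induced ORF1, and 2206 to 10276 CPM elsewhere. glnK, for a nitrogen regulatory protein, was at 25.1 CPM in replicate 2 of uninduced ORF1 and at 0.3 to 1.8 CPM in the other 9 libraries. plaP, for a putrescine transporter, was at 202 and 303 CPM in replicate 1 of uninduced and induced Svi3-3 and at 580.8 to 983 CPM elsewhere. lacZ reads covered 49.63% to 73.72% of the gene in the 4 libraries without IPTG and 95.93% to 99.97% in the 6 with it.

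flu and its neighbour yeeR were low in all 4 Svi3-3 libraries, with flu at 38.1 to 40.1 CPM against 899.9 to 2896 CPM in the other 6 libraries, and yeeR at 7.6 to 11.7 against 29.3 to 74.2 CPM. The nearby genes yeeS and yeeP, named after their values were seen, were called in no comparison, with yeeS at 2.4 to 4.5 against 6 to 11.3 CPM and yeeP, which overlapped, at 4.7 to 9.5 against 9 to 13.7 CPM. The methionine response as a cause is argued against by a log2 fold change of 0.02 for flu in induced ORF1, where all 14 MetJ genes were raised. Loss of flu from all cells with spill-over of reads from other libraries is argued against by a level of at least 2.82% of the other libraries, where the lowest metE library allowed a spill-over of 1.02%. A state of the cells with the Svi3-3 plasmid that is present with and without IPTG is consistent with a difference of -0.06 between induced and uninduced cultures. Antigen 43 is known to switch between on and off phases, and a founding cell in the off phase, loss of the gene in most cells, or an effect of the insert at its uninduced level may each give this value, and none of these was separated.

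The arginine and iron uptake genes differed between replicates within both ORF1 groups, with a median arginine level of 11.11 and 9.84 log2 CPM in uninduced and 7.19 and 10.46 in induced replicates 1 and 2. A swapped label between the ORF1 groups is argued against by the gap of 1.6 log2 CPM between induced and uninduced MetJ medians. Crossed replicate numbers and cultures that differed singly cannot be told apart from the correlation of -0.18 between same-numbered libraries, because there are 2 pairs. No biological explanation was tested.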
